A study of Homo sapiens with 40 samples.

How the data were processed

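The data are gene expression values from 40 arrays of LNCaP cells, a human prostate cancer line that responds to androgen. Per the labels, 3 control lines sensitive to MDV3100 and 7 resistant clones were cultured for 3 days and then given 10 µM MDV3100, an antiandrogen also called enzalutamide, or 0.1% DMSO, its solvent, for 24 h. The resistant clones carry the numbers 1, 9, 10, 14, 15, 19 and 24, and the control lines, titled D+E-, D+R- and M+R-, are called control 1, control 2 and control 3 here. The labels do not explain these titles. Each line and treatment has 2 arrays, numbered replicate 1 and replicate 2. The groups hold 6 control DMSO, 6 control MDV3100, 14 resistant DMSO and 14 resistant MDV3100 arrays, and each array was placed by its label alone. Per the labels' protocols, amplified and biotin-labelled RNA was hybridised, and the probe set identifiers are those of an Affymetrix array. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

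The values deposited by the authors are linear signal intensity per probe set, made with MAS5 per the submitters' processing notes; its version was not given in the sources used here. In every array the mean signal intensity after trimming 2% of probe sets at each end was 150, so the deposited values had been scaled to a common level and were not normalized again here. The median signal of an array lay between 10.7 and 18.4 and the 75th percentile between 125.3 and 150.9. The number of arrays limits the precision of every value. All columns of values were matched to a sample by its identifier, the titles gave the groups, and 0 columns were left unmapped.

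Values were converted to log2(value + 16), so that a fold change understates the change of dim genes. Probe sets whose mean over all arrays reached the median of all probe set means were kept, at log2 4.815 or a signal of 12.1, which left 27338 of 54675 probe sets. Gene names came from the platform annotation given with the data, where 41097 probe sets had 1 gene, 1801 had several and 11777 had none. Only probe sets with 1 gene were named. Of the gene identifiers, 54 had no match in the current gene table, and 0 symbols were updated. Each gene was represented by its brightest probe set, which gave 11853 genes. Other probe sets of the same gene can differ from it, as the closing section gives.

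Before the data were examined, 5 comparisons of the groups were fixed, each tested with limma 3.58.1 in R 4.3.3 and Benjamini-Hochberg adjustment over all genes, with adjusted p under 0.05 as a call. The response of the control lines was fitted on 12 arrays with line as a block. The other comparisons took the line as the replicate, from the mean of its arrays. They were the response of the 7 clones, the difference of responses between 7 clones and 3 control lines, and the levels of clones against control lines in DMSO and in MDV3100. A model over all arrays gave the response of each single line and the difference of each clone from the control lines. Calls from it compare these cultures, not lines in general.

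A total of 17 gene lists with 315 members was fixed in advance, from androgen-induced, androgen-repressed and proliferation genes to markers of other cell types. Of the members, 28 had no named probe set and were not analysed here. Lists were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation, each adjusted over the lists of a comparison. For the androgen-induced, androgen-repressed and proliferation lists, the mean response and the mean DMSO level per line were compared by a 2-sided exact permutation test over the 120 splits of the lines. The smallest p this design allows is 0.00833, and the 6 list values were adjusted together.

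The genes named in the text followed a rule fixed in advance. It takes up to 10 rises and 10 falls, the largest among called genes that moved the same way in every line, then a short fixed set that includes KLK3, KLK2, TMPRSS2 and FKBP5, and up to 4 members of each list with the largest differences. For single lines it takes the 3 largest differences among called genes. Of the fixed set, NR3C1 lay below the filter, and its other members are not reported here.

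Replicate 1 and replicate 2 were treated as 2 sets of arrays because arrays with the same label differed between them. Each comparison was therefore refitted within each set. In the report, a pair of values in square brackets gives replicate 1 and replicate 2 arrays alone, for named genes and for the medians of lists. The replicate numbers pair the DMSO and MDV3100 arrays of a line. Over the 20 such pairs, deviations from the group means correlated at r = 0.479 to 0.874, and within a line the shift between replicates in DMSO and in MDV3100 correlated at r = 0.593 to 0.903, median 0.845. These are correlations across genes, which are not independent replicates. A fit with each pair as its own block, added after the data were seen, is given where it moved a count by over 1.5 times. For groups of lines it counts the 2 pairs of a line as separate replicates, so its p-values rest on pairs and not on lines.

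Alternatives were other pseudocounts, quantile normalization, other filters, the median of a gene's probe sets, an intensity trend in the variance, a minimum fold change, arrays as replicates, blocks for the replicate number and leaving out each line or replicate. Each fit was tested on simulated data with 11853 genes, of which 100 were changed by 1 and 100 by 2 on the log2 scale. The simulated noise was independent between genes and held no difference between replicate sets and no pairing of arrays. The real data have both, so the rates below may not hold for them. For the response of the control lines 76% and 97% were recovered, with 4.42% false among the calls. For the response of the clones 100% and 100% were recovered, with 7.41% false. The difference of responses gave 98% and 100%, with 3.88% false. The DMSO levels gave 91% and 97%, with 3.09% false, and the MDV3100 levels 92% and 100%, with 4.95% false. For a single clone the figures were 22% and 79% for its response, with 6.48% false, and 43% and 91% for its difference from the control lines, with 6.29% false. Figures were drawn with matplotlib 3.10.9.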

Results

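Gene expression was measured on 40 arrays of LNCaP prostate cancer cells. There were 3 control lines, labelled sensitive to the antiandrogen MDV3100, and 7 resistant clones. Each was treated for 24 h with 10 µM MDV3100 or with 0.1% DMSO, with 2 replicate arrays per line and treatment. The groups held 6 control DMSO, 6 control MDV3100, 14 resistant DMSO and 14 resistant MDV3100 arrays. The labels set up the question of how sensitive and resistant cells differ before and under the drug. Values are MAS5 signals, and differences are on the log2(signal + 16) scale.

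Arrays with the same label differed between the replicate sets. Profiles here are log2 values with each gene's mean over the 40 arrays subtracted. A large difference between the sets therefore gives negative r across them by itself, and r below 0 does not mean that raw signals ran opposite. Over all genes, the profile of an array correlated with the other replicate of its own label at a median r of -0.408 (range -0.641 to 0.38), and 30 of the 40 arrays had r below 0. The other treatment of the same line and replicate correlated at a median r of 0.782 (range 0.402 to 0.854). For 0 of the 40 arrays was the other replicate the best match, and for 36 the best match lay in the same replicate set. These r are across genes, which are not independent replicates. With lines averaged over treatments, control 2 of replicate 2 matched clone 1 of replicate 1 best (r = 0.748) and its own label at r = -0.328. Clone 1 of replicate 2 matched clone 19 of replicate 1 best (r = 0.744), and control 3 of replicate 2 matched clone 15 (r = 0.633). UGT2B17, an enzyme that inactivates androgens by glucuronidation, had a DMSO signal of 23.3 on the replicate 1 array labelled clone 1 and 980.2 on the replicate 2 array. On the arrays labelled control 2 its DMSO signal was 731.6 and 60.3. All groups below are those of the labels, "clones" and "control lines" mean the arrays so labelled, and pairs in square brackets give the value in replicate 1 arrays alone and in replicate 2 arrays alone.

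**Figure D1:**
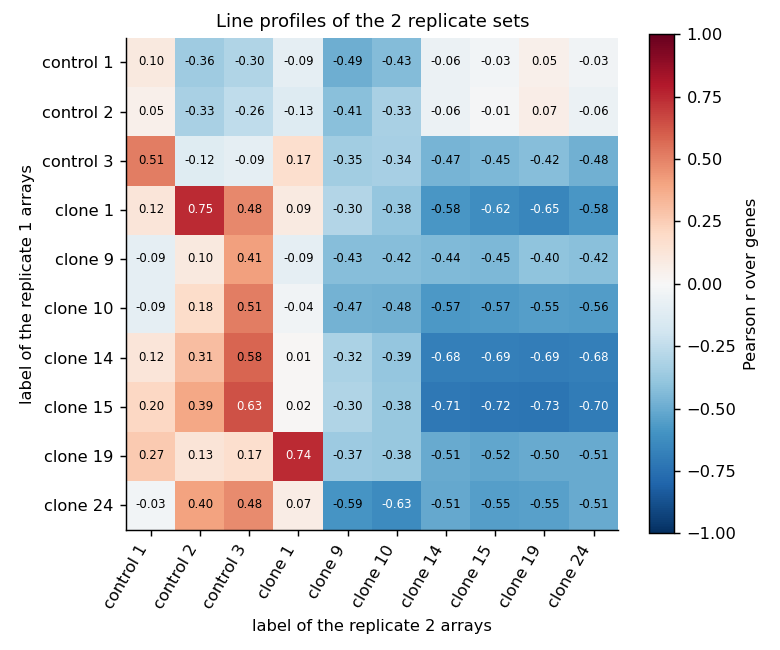
Pearson r over genes between the profile of each line in replicate 1 (vertical axis) and in replicate 2 (horizontal axis), with DMSO and MDV3100 arrays of a line averaged. Profiles are log2 values with each gene's mean over all arrays subtracted. Red cells are positive and blue cells negative. The diagonal, which pairs each label with itself, runs from -0.724 for clone 15 to 0.0956 for control 1.

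Genes that androgen induces in prostate cells fell less under MDV3100 in the resistant clones than in the control lines, with the same direction in each replicate set. Over the 31 measured members, the mean response to MDV3100 was -0.64 ± 0.20 (SD, n = 3 control lines) and -0.15 ± 0.14 (SD, n = 7 clones). All 7 clones lay above all 3 control lines. The difference of 0.50 had p = 0.00833 by a 2-sided exact permutation test, the smallest p the design allows, or 0.025 adjusted over the 6 list values. In replicate 1 arrays alone it was 0.37 (exact p = 0.0417, adjusted 0.0626) and in replicate 2 arrays alone 0.62 (exact p = 0.0167, adjusted 0.0501). Androgen-repressed genes moved the other way, rising by a mean of 0.45 ± 0.07 (SD, n = 3) in control lines and 0.09 ± 0.09 (SD, n = 7) in clones, a difference of -0.36 with exact p = 0.00833 and an adjusted p of 0.025. Within the sets this difference was -0.19 (exact p = 0.0167, adjusted 0.0501) and -0.53 (exact p = 0.00833, adjusted 0.05), so for neither list did a set alone pass after adjustment.

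The single lines differed in how far these genes moved. In replicate 1, the androgen-induced genes had mean responses of -0.74, -0.70 and -0.72 in control 1, control 2 and control 3. Clones 9, 10 and 14 had -0.65, -0.66 and -0.64 in that set, and clone 15 had -0.33. Clones 1, 19 and 24 had -0.05, -0.04 and -0.06. In replicate 2, the control lines had -0.93, -0.17 and -0.61, and the 7 clones lay between -0.17 and 0.18. Transcripts of proliferation, such as those for DNA replication and mitosis, had a mean response of -0.38 ± 0.14 (SD, n = 3) in control lines and -0.20 ± 0.08 (SD, n = 7) in clones. That difference of 0.18 had exact p = 0.025 and an adjusted p of 0.05, with 0.26 (exact p = 0.00833, adjusted 0.05) in replicate 1 and 0.10 (exact p = 0.45, adjusted 0.54) in replicate 2.

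**Figure D2:**
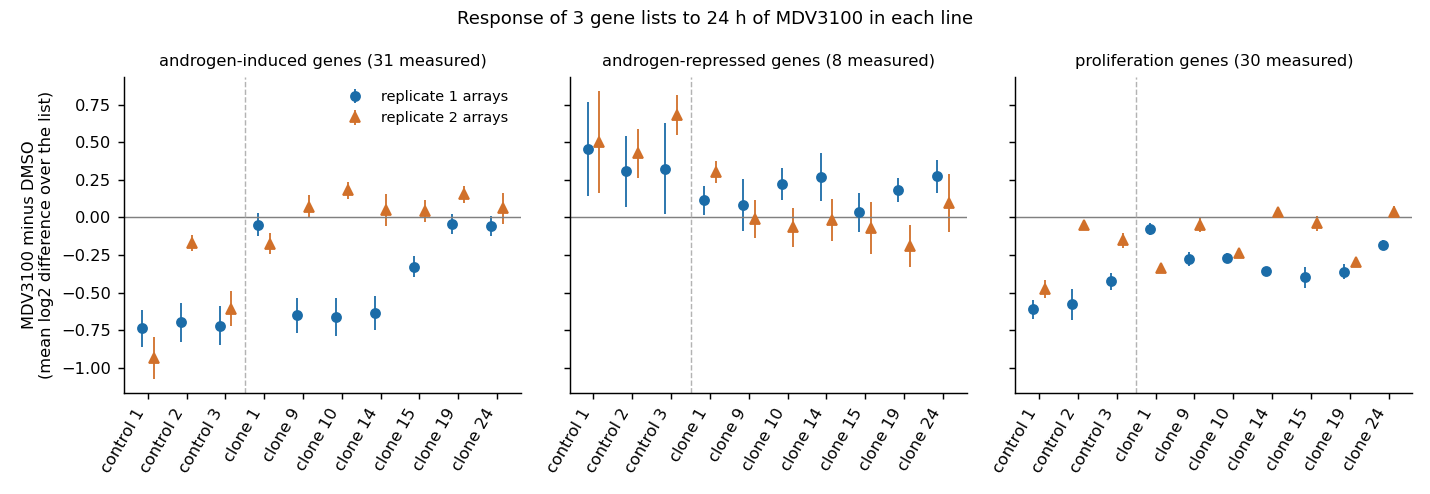
Mean log2 difference between MDV3100 and DMSO over the members of 3 gene lists (vertical axis) for each line (horizontal axis), with circles for replicate 1, triangles for replicate 2 and bars for the SE over genes; the dashed line parts control lines from clones. In replicate 1 the androgen-induced genes of clones 9, 10 and 14 lie between -0.66 and -0.64, close to the control lines, and in replicate 2 all clones lie between -0.17 and 0.18.

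The control lines were compared with and without MDV3100 to find what the drug does in sensitive cells. MDV3100 lowered ADH1C, an alcohol dehydrogenase, by a log2 difference of -2.14 ± 0.19 (SE, n = 6 arrays per treatment from 3 lines) [-2.11, -2.17]. It lowered ST6GALNAC1, a sialyltransferase that modifies mucin-type glycans, by -2.02 ± 0.19 [-1.93, -2.11]. These SE come from the fit on arrays with line as a block, and not from differences of line means. The mean signal of ST6GALNAC1 under MDV3100 was 10.7, below the filter signal of 12.1, so the pseudocount limits the size of its fall. WWTR1, the coactivator TAZ of the Hippo pathway, fell by 1.77 [-1.71, -1.82], and DDIAS and STYXL2 fell by 1.17 [-1.40, -0.93] and 1.14 [-1.49, -0.79]. TMTC2, IQGAP2, FHDC1 and PLA2G5 fell by 0.92 [-0.96, -0.88], 0.89 [-0.77, -1.01], 0.84 [-0.85, -0.83] and 0.74 [-0.85, -0.63]. The 3 genes called higher were IL1RN, which encodes the interleukin-1 receptor antagonist (1.30 ± 0.17) [1.40, 1.20], ABCG2, a drug efflux pump (1.09 ± 0.17) [0.97, 1.21], and CSMD1 (0.90 ± 0.10) [0.86, 0.95]. CYP1A2, a drug-metabolising cytochrome P450, was not among them in the pooled fit. Limma called it in each set alone, at 2.09 in replicate 1 (adjusted p = 0.000235) and 1.85 in replicate 2 (adjusted p = 0.0272).

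Known androgen targets were lower under MDV3100 in the control arrays, and whether they were called depended on the pairing of DMSO and MDV3100 arrays. The planned fit took line as the block and called none of those below. With each pair as a block, added after the data were seen, limma called KLK2 (adjusted p = 0.0170), TMPRSS2 (0.0239) and FKBP5 (0.0110), and not KLK3 (0.118). Those p-values count the 2 pairs of a line as separate replicates. KLK2, a prostate protease, had a mean signal of 2248 ± 547 in DMSO and 961 ± 811 in MDV3100 (SD, n = 6 arrays each), a log2 difference of -1.50 ± 0.31 [-1.98, -1.02] with adjusted p = 0.147, and 0.000258 and 0.333 in the sets. KLK3, which encodes prostate-specific antigen, had 2942 ± 1072 and 2002 ± 723, a difference of -0.53 ± 0.29 [-0.74, -0.33] (adjusted p = 0.781). TMPRSS2, a membrane protease, differed by -1.05 [-1.42, -0.68] (adjusted p = 0.330, and 0.00440 and 0.374 in the sets) and FKBP5, an immunophilin that binds steroid receptor complexes, by -0.65 [-0.65, -0.64] (adjusted p = 0.446). TRPM8, a cold-sensing ion channel, differed by -2.27 in each replicate set, with adjusted p = 0.0176 in replicate 1 and 0.00842 in replicate 2, and with 0.330 in the pooled fit. OPRK1, the kappa opioid receptor, differed by 1.79 (adjusted p = 0.494), with 2.20 in replicate 1 (adjusted p = 0.000235) and 1.37 in replicate 2 (adjusted p = 0.0817).

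As groups, the androgen-induced and the proliferation genes shifted down. Of the 31 androgen-induced genes 29 had a negative difference, with a median of -0.54 [-0.57, -0.58]. None passed over all genes in the pooled fit, 9 in replicate 1 alone and 1 in replicate 2 alone, and 14 were lower in the pooled fit when adjusted over the list alone. Camera gave adjusted p = 1.22e-19, and adjusted p = 0.0377 with an estimated correlation. With an estimated correlation the sets alone did not pass, at adjusted p = 0.131 and 0.480. All 30 proliferation genes were negative, with a median of -0.37 [-0.54, -0.20], among them the replication-licensing genes CDC6 (-0.71) [-0.82, -0.60] and MCM5 (-0.70) [-0.94, -0.45]. None of these 30 passed over all genes and 1 was lower when adjusted over the list alone. Their camera adjusted p was 5.79e-17, and adjusted p = 0.162 with an estimated correlation. Of 8 androgen-repressed genes 7 were positive, with a median of 0.30 [0.16, 0.40], and limma called 0 of the 8 over all genes and 0 adjusted over the list alone. OPRK1 and CAMK2N1 (0.63) [0.17, 1.09] had the largest differences. This list had a camera adjusted p of 0.0165, and adjusted p = 0.248 with an estimated correlation. Glucocorticoid-induced genes shifted down, led by ZBTB16 (-1.09) [-1.33, -0.84], a zinc finger transcription factor, with a list median of -0.14 [-0.17, -0.23] and adjusted p = 0.0205, and 3 of 9 were lower when adjusted over the list alone. With an estimated correlation the adjusted p = 0.170. Cholesterol and fatty acid synthesis genes (15 of 19 negative, median -0.09 [-0.13, -0.08], adjusted p = 0.0433) and unfolded protein and amino acid stress genes (13 of 21 positive, median 0.10 [0.02, 0.10], adjusted p = 0.0231) had no member called. With an estimated correlation their adjusted p = 0.162 and adjusted p = 0.20. Of 9 drug transport genes, ABCG2 alone was called, and 2 passed when adjusted over the list alone (camera adjusted p = 0.231).

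By limma, 12 of 11853 genes changed in the control lines, 3 up and 9 down, and 865 had an unadjusted p under 0.05. This fit on arrays differs from that of the clones, so the 2 counts cannot be set side by side, and on 3 differences of line means, the form used for the clones, limma called 718 (378 up, 340 down). Replicate 1 arrays alone gave 140 (52 up, 88 down) and replicate 2 arrays alone 14 (5 up, 9 down). Of the 140, 134 had the same direction in replicate 2, and 8 genes were called in both sets in the same direction, against 0.0888 for independent lists. With each pair of DMSO and MDV3100 arrays as a block, which counts the 2 pairs of a line as replicates, the count was 306 (148 up, 158 down). Without control 1 or without control 3 limma called 0 genes, with 241 and 523 at unadjusted p under 0.05. The actin 3' to 5' ratio, a sign of RNA quality, averaged 5.12 ± 1.28 in MDV3100 and 3.79 ± 0.529 in DMSO on the replicate 1 control arrays (SD, n = 3 each), and 3.57 ± 0.33 and 3.46 ± 0.216 in replicate 2.

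The same comparison in the resistant clones asks what the drug still does there, and most of these changes were larger in replicate 1. CYP1A2 rose by 1.07 ± 0.10 (SE, n = 7 clones) [1.73, 0.42], ADRA2A, an adrenergic receptor, by 0.66 [0.83, 0.49], and PIGR, which carries antibodies across epithelia, by 0.65 [0.24, 1.05]. CYP1A2 was not called by limma in replicate 2 alone (adjusted p = 0.624). There its signal went from 43.3 to 276.1 in clone 1 and lay between 18.2 and 40.7 on the arrays of the other clones. MYLK, RFX6 and SOX9, a transcription factor of epithelial progenitors, rose by 0.55 [0.56, 0.53], 0.51 [0.50, 0.52] and 0.50 [0.69, 0.31]. IGFBP3, UNC13C, PRSS2 and LEF1 rose by 0.46 [0.68, 0.24], 0.44 [0.43, 0.46], 0.43 [0.64, 0.22] and 0.43 [0.73, 0.13]. ADH1C, TRPM8, ST6GALNAC1 and WWTR1 fell by 1.09 [-2.11, -0.08], 0.98 [-1.67, -0.30], 0.88 [-1.35, -0.41] and 0.75 [-1.23, -0.27] in the pooled arrays, and none of these 4 was called in replicate 2 alone, where their adjusted p lay between 0.433 and 0.951. ELOVL7, STYXL2 and DPP4 fell by 0.59 [-0.94, -0.24], 0.50 [-0.86, -0.15] and 0.47 [-0.91, -0.03], and CDCA7, FAM111B and TMTC2 by 0.45 [-0.51, -0.38], 0.44 [-0.74, -0.13] and 0.43 [-0.83, -0.04]. Of the prostate markers, KLK2 differed by -0.56 [-1.03, -0.09] (adjusted p = 0.182), KLK3 by -0.22 [-0.39, -0.05] (adjusted p = 0.427), TMPRSS2 by -0.20 [-0.45, 0.04] (adjusted p = 0.327) and FKBP5 by -0.13 [-0.29, 0.03] (adjusted p = 0.220).

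Proliferation genes shifted down in the clones as well, with all 30 negative and a median of -0.19 [-0.26, -0.12]. MCM5 (-0.31) [-0.41, -0.21] was the 1 member called over all genes, and 25 were lower when adjusted over the list alone. Camera gave adjusted p = 4.35e-19, and adjusted p = 0.133 with an estimated correlation. The androgen-induced genes had a median of -0.13, with TRPM8 called and 6 lower when adjusted over the list alone, and camera gave adjusted p = 0.000181. With an estimated correlation the adjusted p = 0.547. In replicate 1 their median was -0.28 (camera adjusted p = 1.46e-09), and adjusted p = 0.308 with an estimated correlation. In replicate 2 it was 0.03 (camera adjusted p = 0.231). Among growth factor receptor and PI3K genes, IGFBP3 rose, and the epidermal growth factor receptor gene EGFR (-0.24) [-0.27, -0.22] and the feedback inhibitor SPRY1 (-0.41) [-0.37, -0.44] fell, 3 of 17 members over all genes and 5 adjusted over the list alone (camera adjusted p = 0.551).

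By limma 60 genes changed in the clones, 24 up and 36 down. With arrays as replicates and line as a block, the form used for the control lines, limma called 0, with 317 at unadjusted p under 0.05. Replicate 1 arrays alone gave 224 (86 up, 138 down), of which 139 had the same direction in replicate 2. Replicate 2 arrays alone gave 0, with 1216 at unadjusted p under 0.05. With each pair as a block, which counts the 2 pairs of a clone as replicates, the count was 162 (50 up, 112 down). With an intensity trend in the variance limma called 0, with 1872 at unadjusted p under 0.05. Without clone 24 it was 239, and it was 6 to 10 without clone 9, 10, 14, 15 or 19. The actin 3' to 5' ratio of the clones averaged 4.06 ± 0.46 in DMSO and 4.37 ± 0.532 in MDV3100 in replicate 1 (SD, n = 7 each), and 3.14 ± 0.275 and 3.02 ± 0.349 in replicate 2.

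The difference of the 2 responses was tested directly. In the pooled arrays ST6GALNAC1, NNMT, a nicotinamide-methylating enzyme, and WWTR1 went down further in the control lines than in the clones, with clones minus control lines at 1.14 ± 0.16 (SE, 7 clones and 3 control lines) [0.59, 1.70], 1.08 ± 0.19 [1.15, 1.02] and 1.02 ± 0.19 [0.48, 1.55]. NNMT had mean responses of -1.18 in control lines and -0.10 in clones. In replicate 1, ST6GALNAC1 went from a mean signal of 89.2 to 11.5 in control lines and from 51.1 to 10.4 in clones. Both ended below the filter signal of 12.1, so its 0.59 there goes with the lower DMSO level of the clones. In replicate 2 it went from 109 to 9.93 in control lines and from 226 to 187 in clones. PMEPA1 (0.93) [1.08, 0.78] and TMPRSS2 (0.85) [0.97, 0.72], both androgen targets, and FKBP5 (0.52) [0.36, 0.67] differed in the same direction, as did TM4SF1 (0.91) [0.80, 1.03], F5, the coagulation factor V gene (0.90) [0.87, 0.94], and LRRC36 (0.86) [1.04, 0.68]. CCDC141 and AFF3 differed by 1.04 [-0.08, 2.15] and 0.92 [-0.04, 1.88], with none of it in replicate 1. In the other direction, OPRK1 had a mean response of 1.79 in control lines and 0.21 in clones, a difference of -1.58 ± 0.26 [-1.48, -1.67]. DAPK1, a death-associated kinase, MID1, a ubiquitin ligase, and the adhesion gene AMIGO2 differed by -1.18 [-0.86, -1.50], -1.05 [-0.81, -1.29] and -1.01 [-1.24, -0.80]. MAN1A1, PKIB and SI differed by -0.99 [-1.18, -0.80], -0.96 [-0.99, -0.93] and -0.89 [-0.95, -0.83]. DDC, COLEC12 and COL5A2 differed by -0.93 [-0.06, -1.80], -0.89 [-0.27, -1.50] and -0.88 [-0.61, -1.15]. KLK2 (0.95 [0.96, 0.93], adjusted p = 0.210) and KLK3 (0.31 [0.34, 0.28], adjusted p = 0.517) did not pass.

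**Figure D3:**
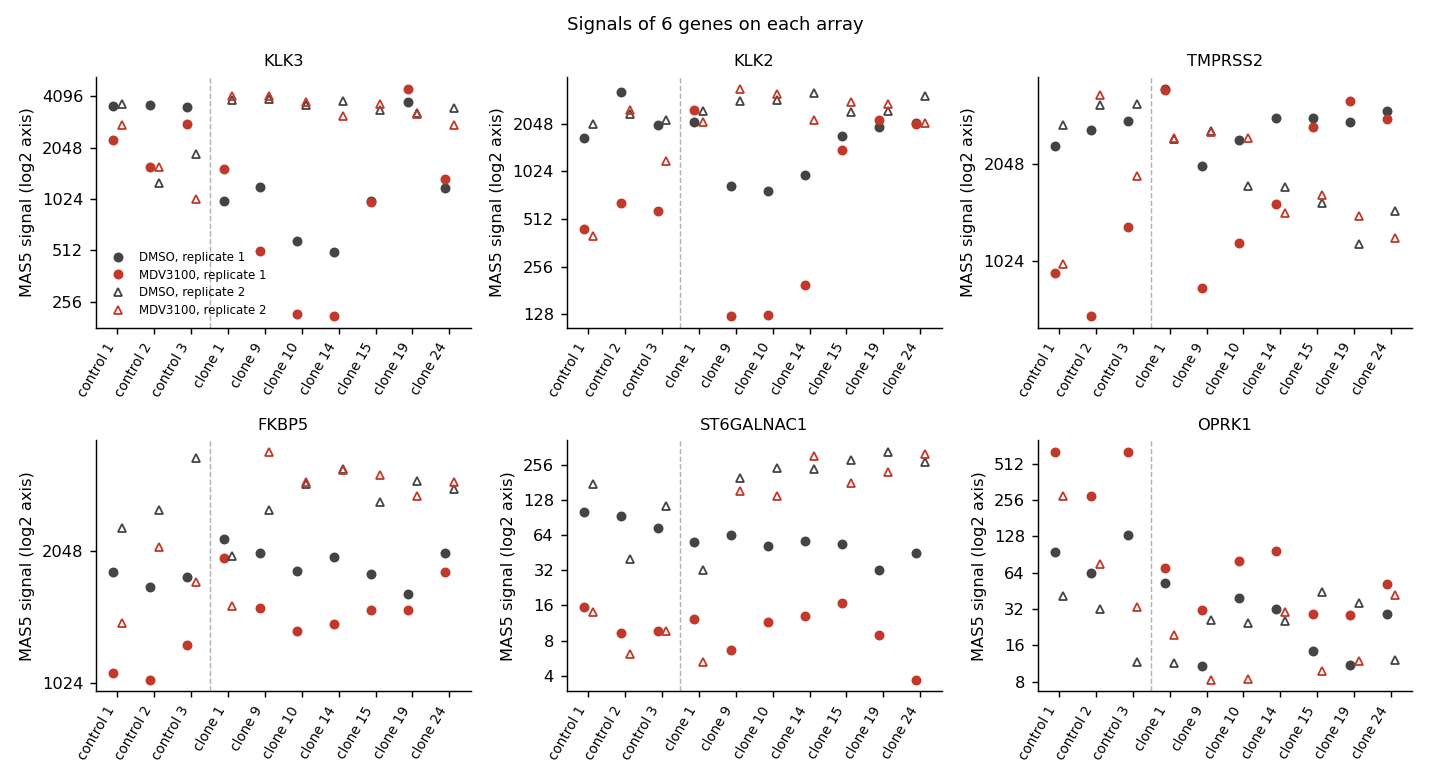
MAS5 signal on a log2 axis (vertical) of 6 genes on each array, by line (horizontal), with grey for DMSO, red for MDV3100, filled circles for replicate 1 and open triangles for replicate 2; the dashed line parts control lines from clones. For OPRK1 the replicate 1 control arrays have a mean of 96.3 in DMSO and 518 in MDV3100, and the replicate 1 clones 27.0 and 55.3.

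By list, 28 of 31 androgen-induced genes had a positive difference, with a median of 0.52 [0.34, 0.67]. Of these 6 were higher over all genes, and 22 were higher and 1 lower when adjusted over the list alone. Camera gave adjusted p = 5.04e-18, and adjusted p = 0.0549 with an estimated correlation. Of 8 androgen-repressed genes 7 were negative, with a median of -0.34 [-0.09, -0.47], OPRK1 called over all genes, and 1 higher and 5 lower when adjusted over the list alone. The adjusted p = 0.00109, and adjusted p = 0.0549 with an estimated correlation. The glucocorticoid list was shifted up, with a median of 0.23 [0.24, 0.21], FKBP5 called and 4 higher when adjusted over the list alone (adjusted p = 0.00109), and adjusted p = 0.0976 with an estimated correlation. Proliferation genes were positive for 29 of 30, with a median of 0.18 [0.25, 0.10], 0 called over all genes and 4 when adjusted over the list alone (adjusted p = 5.72e-07), and adjusted p = 0.167 with an estimated correlation. Hypoxia and glycolysis (median 0.11 [0.08, 0.08], adjusted p = 0.0196), cholesterol (0.10 [0.04, 0.17], adjusted p = 0.0149) and polyamine synthesis genes (0.13 [0.22, 0.00], adjusted p = 0.0365) had no member called under either adjustment. With an estimated correlation their adjusted p = 0.0976, adjusted p = 0.167 and adjusted p = 0.116.

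By limma the responses differed for 85 genes, 36 with a positive and 49 with a negative difference. In replicate 1 arrays alone 1 gene, OPRK1 (-1.48), was called. In replicate 2 arrays alone limma called 0, with 1306 at unadjusted p under 0.05, and with each pair as a block it called 0, with 1415. Without control 1 limma called 0, with 1128 at unadjusted p under 0.05, and without clone 19 it called 27.

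Before the drug, few genes separated clones from control lines once both replicate sets were averaged. HGD, an enzyme of tyrosine breakdown, was higher in the clones by 1.28 ± 0.16 (SE, 7 clones and 3 control lines) [1.04, 1.53]. PIGL, of glycosylphosphatidylinositol anchor synthesis, and PKLR, a pyruvate kinase, were higher by 0.61 [0.61, 0.61] and 0.61 [0.51, 0.70], though with the median of its probe sets PIGL stood at -0.00192. MICOS13, GADD45B, a stress-response gene, and ARL16 were higher by 0.56 [0.39, 0.73], 0.54 [0.33, 0.76] and 0.54 [0.13, 0.95], and ATG12, of autophagy, SARNP and FAM216A by 0.53 [0.25, 0.80], 0.50 [0.51, 0.49] and 0.42 [0.17, 0.68]. GLIS2, a zinc finger transcription factor, and OPRK1 were lower, at -0.76 [-0.90, -0.62] and -0.75 [-1.43, -0.07]. CYFIP2, SCAF1 and ZNF385A were lower at -0.50 [-0.12, -0.88], -0.47 [-0.25, -0.69] and -0.45, of which ZNF385A stood at 0.00372 in replicate 1 and -0.91 in replicate 2. KLK3 differed by -0.47 (adjusted p = 0.266), with -1.74 in replicate 1 and 0.81 in replicate 2. The DMSO level of the androgen-induced list differed by 0.00234 between clones and control lines (exact p = 0.958), with -0.17 in replicate 1 (exact p = 0.117, adjusted 0.14) and 0.18 in replicate 2 (exact p = 0.0417, adjusted 0.075). The androgen-repressed list differed by -0.02 (exact p = 0.983), with -0.79 in replicate 1 (exact p = 0.0417, adjusted 0.0626) and 0.75 in replicate 2 (exact p = 0.05, adjusted 0.075), and the proliferation list by 0.02 (exact p = 0.8).

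Steroid synthesis and metabolism enzymes were higher in the clones as a list, with 8 of 10 positive and a median of 0.28 [0.14, 0.41]. The aldo-keto reductases AKR1C2 (0.92) [1.06, 0.78], AKR1C3 (0.79) [1.09, 0.49] and AKR1C1 (0.79) [0.89, 0.68], which reduce steroids, had the largest differences. Limma called 0 of the 10 over all genes and 6 higher when adjusted over the list alone. The camera adjusted p = 0.00932, and adjusted p = 0.119 with an estimated correlation. In the sets alone the list did not pass, at camera adjusted p = 0.187 and 0.131. Interferon-stimulated genes were positive for 14 of 17 in the pooled arrays, with a median of 0.18, led by ISG20 (0.72) [0.62, 0.82] and OAS1 (0.58) [0.57, 0.58]. Here 0 were called over all genes and 5 were higher and 1 lower when adjusted over the list alone. The camera adjusted p = 0.00932, and adjusted p = 0.334 with an estimated correlation. In replicate 1 the median was 0.38 (camera adjusted p = 0.00704), and adjusted p = 0.60 with an estimated correlation. In replicate 2 it was -0.03 with 7 of 17 positive (camera adjusted p = 0.807), and the difference between the sets was not tested.

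By limma 14 genes differed in DMSO, 9 higher and 5 lower in the clones. Within a replicate set there were many more, 725 in replicate 1 (432 higher, 293 lower) and 1221 in replicate 2 (465 higher, 756 lower). Only 163 of the 725, or 22.5%, had the same direction in replicate 2. Both sets called 8 genes in the same direction and 71 in opposite directions, against 35.6 in the same direction for independent lists. The number of opposite calls expected for independent lists was not computed, so not all 71 need be true reversals. ETV1, an ETS transcription factor, was the largest example, at -4.61 in replicate 1 (adjusted p = 0.0289) and 4.12 in replicate 2 (adjusted p = 0.0377), where signals as low as 0.3 in both sets leave the size of these differences to the pseudocount. RIPOR2 and KLHL1 were lower in the clones of replicate 1, at -4.09 and -3.61, with 1.56 and 1.05 in replicate 2. SLC4A4, a bicarbonate transporter, was lower in the clones of replicate 2 at -3.45, with 0.24 in replicate 1. Without clone 1 the pooled count was 2126, and with the replicate number as a block it was 630. Leaving out any other line gave 0 or 1 by limma, with 1717 to 2767 at unadjusted p under 0.05.

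Under MDV3100, LXN, a carboxypeptidase inhibitor, PHLDB2 and GRIN3A, a glutamate receptor subunit, were higher in the clones than in the control lines by 2.40 ± 0.53 [2.09, 2.71], 2.21 ± 0.41 [0.88, 3.54] and 2.10 ± 0.40 [2.35, 1.86] (SE, 7 clones and 3 control lines). HPGD, which degrades prostaglandins, was higher by 1.74 [-0.08, 3.56], from replicate 2 alone. VIM, the mesenchymal filament vimentin, and SNAI2, a transcription factor of epithelial-mesenchymal transition, were higher by 1.67 [1.16, 2.18] and 1.55 [0.46, 2.64], and SNAI2 was not called in replicate 1 alone (adjusted p = 0.0679). AFF3, HGD, DLX1 and CCDC141 were higher by 1.67 [1.20, 2.15], 1.62 [0.97, 2.28], 1.52 [0.72, 2.32] and 1.43 [0.41, 2.44]. CBLN2 and SLITRK3, of synapse formation, were lower by -3.04 ± 0.63 [-2.27, -3.82] and -2.46 ± 0.44 [-3.52, -1.41], and OPRK1 by -2.32 ± 0.32 [-2.90, -1.74]. DDC, an amino acid decarboxylase, COLEC12 and the cytokine TNFSF15 were lower, at -1.91 [-0.85, -2.96], -1.66 [-1.69, -1.62] and -1.56 [-1.79, -1.34]. SCD5, a fatty acid desaturase, was lower at -1.40 [-0.33, -2.47] and was not called in replicate 1 alone (adjusted p = 0.496). SLC4A4 (-1.81) [0.26, -3.89], KLHL1 (-1.67) [-3.70, 0.35] and RIPOR2 (-1.46) [-3.77, 0.85] were lower in the pooled arrays and in 1 set each. FKBP5 was higher by 0.58 [0.48, 0.67] (adjusted p = 0.0138). KLK2 (0.77 [0.27, 1.26], adjusted p = 0.345), TMPRSS2 (0.51 [1.06, -0.04], adjusted p = 0.134) and KLK3 (-0.15 [-1.40, 1.09], adjusted p = 0.839) did not pass. In the control lines PHLDB2, HPGD, SNAI2, DLX1, CCDC141 and OAS1 had a mean below the filter level, as did GLIS2 in the clones in DMSO, so the pseudocount limits the size of their differences.

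Of the androgen-induced genes 11 of 31 were higher in the clones under MDV3100, with a list median of 0.51 [0.39, 0.69]. Among them were HPGD, the prostaglandin receptor gene PTGER4 (1.12) [1.07, 1.17], the prostate membrane transporter gene SLC45A3 (1.07) [1.04, 1.10] and AZGP1 (1.03) [1.77, 0.29], and 15 were higher when adjusted over the list alone. Their camera adjusted p was 1.87e-08, and adjusted p = 0.208 with an estimated correlation. Among androgen-repressed genes, OPRK1 and BCL2 (-0.91) [-0.48, -1.34], an inhibitor of apoptosis, were lower, 2 of 8 over all genes and 2 adjusted over the list alone. The list median was -0.26 [-0.91, -0.28] (camera adjusted p = 0.0443), and adjusted p = 0.323 with an estimated correlation. Proliferation genes had a median of 0.20 [0.31, 0.15], with 4 of 30 called higher, and 4 adjusted over the list alone (camera adjusted p = 0.000531), and adjusted p = 0.622 with an estimated correlation. In the glucocorticoid list (median 0.31 [0.20, 0.39]) FKBP5 and the kinase gene SGK1 (0.66) [0.92, 0.39] were higher, 2 of 9 over all genes, and 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0252), and adjusted p = 0.221 with an estimated correlation. Steroid enzymes (9 of 10 positive, median 0.25 [0.31, 0.01], 0 called by limma over all genes and 0 adjusted over the list alone, camera adjusted p = 0.0231) shifted up in the pooled arrays. So did interferon-stimulated genes (13 of 17 positive, median 0.23 [0.45, 0.01], OAS1 called at 0.67 [0.34, 1.00], 1 adjusted over the list alone, camera adjusted p = 0.0140), and both medians were 0.01 in replicate 2. With an estimated correlation the 2 lists had adjusted p = 0.208 and adjusted p = 0.324. Among growth factor genes, IGF1R (0.91) [1.20, 0.62], FGFR3 (0.82) [0.59, 1.04], INPP4B (0.60) [0.24, 0.97] and SPRY2 (0.41) [0.51, 0.30] were higher and ERBB2 (-0.59) [0.07, -1.24] and SPRY1 (-0.51) [-0.68, -0.34] lower, with 7 called when adjusted over the list alone (camera adjusted p = 0.956).

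No list of markers of other cell types passed camera, in the pooled arrays or in a set alone. The mean DMSO level of the mesenchymal list, relative to the control lines of the same set, was -0.49 to 0.03 in clones 9 to 24 and -0.31 in clone 1 of replicate 1. In replicate 2 it was 0.41 to 0.70 and -0.27, a difference between the sets that was not tested. Of the mesenchymal and fibroblast markers, VIM and SNAI2 were higher and the collagen gene COL1A1 (-0.61) [-1.0, -0.21] lower in the clones under MDV3100, with 5 of 9 called when adjusted over the list alone (camera adjusted p = 0.618). Of 4 neuroendocrine markers measured, ENO2 (-0.56) [-0.76, -0.36] was lower there, with 2 called adjusted over the list alone (camera adjusted p = 0.956), and of 14 luminal markers SPDEF (0.49) [0.96, 0.02] was higher, with 3 called adjusted over the list alone (camera adjusted p = 0.956). Of the basal markers only ITGA6 was measured, at -0.35 [-1.56, 0.87] and not called in the pooled arrays, and 0 leukocyte markers lay above the filter. Over the 5 comparisons 23 list shifts passed at the preset correlation. The fall of the androgen-induced genes in the control lines was the 1 that held with an estimated correlation, in the pooled arrays and in neither set alone.

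By limma 1062 genes differed under MDV3100, 557 higher and 505 lower in the clones. Replicate 1 arrays alone gave 1068 (655 higher, 413 lower) and replicate 2 arrays alone 2326 (854 higher, 1472 lower). Both sets called 36 genes in the same direction and 154 in opposite directions, against 98.5 in the same direction for independent lists. Here too the number of opposite calls expected for independent lists was not computed. The count was 8 without control 1. Whether more genes differed under MDV3100 than in DMSO was not tested, and without clone 1 the counts were 2201 and 2126.

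Single lines gave no calls in the fit over all arrays, where the spread between the replicates of a label sets the error. For the response to MDV3100, limma called 0 genes in each of the 10 lines. At unadjusted p under 0.05 there were 338, 48 and 51 genes in control 1, 2 and 3, and 8 to 184 in the clones. With each pair of arrays as a block, control 1 had 102 genes (37 up, 65 down), led by TRPM8 (-3.01 ± 0.56, SE), OPRK1 (2.46 ± 0.49) and ST6GALNAC1 (-2.28 ± 0.42), and the other 9 lines had 0. For the difference of each clone from the control lines in DMSO, limma called 0 genes in each of the 7 clones, with 80 in clone 1 to 425 in clone 9 at unadjusted p under 0.05.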

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

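The tests of wrong labels, of a shift shared by a replicate set, of the starting level and of a single replicate set were chosen after the result was seen, as was the fit with each pair as a block; the splits of the samples and the tests of RNA quality and of which arrays reversed were planned before it.

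The first pattern is that replicates of a label differ. Wrong line labels are a candidate explanation for the control lines and clone 1, since all 4 of these replicate 2 lines matched another line of replicate 1 at r over 0.5. Control 1 passed this cut narrowly, at r = 0.51 with control 3 (own label 0.0956). That is another control line, so this match would not change its group. Control 3 passed it with clones 10, 14 and 15 (r = 0.513, 0.582 and 0.633), so its match does not point to a single line. For clones 9 to 24 the highest r of any of them with a replicate 1 line was 0.0657. An exchange alone among these 40 arrays does not account for that. An exchange combined with a shift of these arrays stays open, since a large difference between the sets lowers r by itself. The median r between the replicate shifts of control lines and clones was -0.188. It cannot decide on a shift shared by all arrays of a set. If the labels of the control lines were exchanged, their shifts are differences between lines. On the main axis of variation between arrays (first principal component, 42.9% of the variance), clones 9 to 24 of replicate 2 lay at 23.66 to 51.6. The control lines and clone 1 of replicate 2 lay at -23.15 to -1.376, within the range of replicate 1 (-35.89 to 7.77). This argues against a shared shift as large as that of clones 9 to 24. A smaller shared shift stays open. After the 3' to 5' ratios were removed, the median r between replicates of a line was -0.193 (-0.455 before). This argues against RNA quality, as these ratios measure it, as the whole cause, and leaves open a part of it. An exchange with cells outside these arrays and a real change of clones 9 to 24 between the sets, whose shifts correlated at a median r of 0.71, stay open, and no biological explanation was tested.

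The next pattern is that androgen-induced genes fell less in the clones. A lower level before the drug is argued against for replicate 2 by a clone minus control level of 0.178, and for replicate 1, where the level was -0.173, by r = 0.813 over the 7 clones between level and response (exact permutation p = 0.00476), since clones with a lower level fell more. Both replicate sets had a difference above 0, the smaller being 0.371 in replicate 1 (exact permutation p = 0.0417, adjusted 0.0626). In replicate 2 the adjusted p of this test was 0.0501, so neither set passed after adjustment. Whether a single set carries the difference therefore stays open. Wrong labels stay open, since the androgen-induced genes of 3 clones of replicate 1 (9, 10 and 14) fell by over 0.5 on the log2 scale, close to the control lines. Resistance itself, which the design names, may account for the difference and stays open as a hypothesis, found and tested on the same data.

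The last pattern is that level differences between clones and control lines change sign between the sets. Over the 71 genes called in opposite directions in DMSO, the clones gave a median of 62.6% of the reversal (quartiles 51.4 to 72.3). The control lines gave 37.4% (quartiles 27.7 to 48.6). The genes had been picked for the reversal, which favours genes that moved on both sides. The shares alone therefore cannot decide whether only 1 side changed, and do not say how often genes reverse. Without that choice of genes, limma called 2764 between replicate 1 and replicate 2 of the control lines, with line as a block. This argues against a change of the clone arrays alone. A change on both sides, by labels or by biology, could be the cause and was not told apart here.

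Chance splits of the samples were counted for each of the 5 comparisons. Of 100 splits of the control arrays, 2 gave as many as the real 12 genes, the real split included, and the highest other count was 2518, for a split that mostly follows the replicate number, so the replicate sets are a structure of these samples. Among the 32 splits that part every pair, 1 gave as many, the real one, and the highest other was 0; with each pair as a block the real count was 306 and the highest other 0. For the response of the clones 1 of 64 splits gave as many as 60, the highest other being 1. For the difference of responses it was 1 of 100 with 85, the highest other being 23. For the DMSO levels 3 of 100 gave as many as 14, and the highest other, 1344, set control 2, control 3 and clone 1 against the rest, which again shows a structure other than the labelled groups. For the MDV3100 levels it was 1 of 100 with 1062, the highest other being 596, for control 1, control 3 and clone 1. Each share lies under 5%, so few splits of these samples gave as many genes. This does not exclude chance, since other splits carry the drug, line and set differences as noise. The shares were not adjusted over the 5 comparisons and say nothing of the replicate sets.

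Single samples far from the rest of their group were found in 2 of 26 groups examined, where chance gives about 1 in 20. Clone 1 had an androgen-repressed level in DMSO of -0.89 relative to the control lines, below the other 6 clones, from -1.99 in replicate 1 and 0.206 in replicate 2. The replicate 1 array of control 2 in MDV3100 had an actin 3' to 5' ratio of 6.59, above the other 5 arrays of its group.

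Responses that differed between clones and control lines by a test of the difference numbered 85 genes. Those named were ST6GALNAC1 (1.14), NNMT (1.08), CCDC141 (1.04), WWTR1 (1.02), PMEPA1 (0.931), AFF3 (0.919), TM4SF1 (0.911), F5 (0.904), LRRC36 (0.861), TMPRSS2 (0.847) and FKBP5 (0.516), with a positive difference. The others were OPRK1 (-1.58), DAPK1 (-1.18), MID1 (-1.05), AMIGO2 (-1.01), MAN1A1 (-0.99), PKIB (-0.96), DDC (-0.926), COLEC12 (-0.886), SI (-0.886) and COL5A2 (-0.879). The list responses differed by 0.498 for androgen-induced, -0.362 for androgen-repressed and 0.182 for proliferation genes.

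Signals outside the named genes were found among 4390 probe sets not paired with 1 gene. Of these limma called 3 for the response of the control lines, 8 for that of the clones, 6 for the difference of responses, 24 for the DMSO levels and 314 for the MDV3100 levels.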

How the results depend on the processing

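The fits with each pair as a block, the list shifts in 1 replicate set and the list without glucocorticoid members were added after the data were seen. The difference in androgen-induced response kept its direction and an unadjusted exact p under 0.05 under every alternative run (0.371 to 0.624), as did that of the androgen-repressed genes. In 1 replicate set alone the adjusted p was 0.0626 and 0.0501 for the induced and 0.0501 and 0.05 for the repressed genes, so those calls were lost. Every median count per single clone stayed at 0. Of the values of named genes and of the other 2 lists under alternatives, 1383 kept direction and call, 726 lost the call, 16 gained one, 9 changed sign with a call in either fit and 10 changed sign with none. The latter were FKBP5 and TMPRSS2 in the response of the clones, KLK2, KLK3, TMPRSS2 and the other 2 lists in DMSO, and KLK3 and TMPRSS2 in MDV3100. Other list members were not counted, of which ERBB2 in MDV3100 stood at 0.07 in replicate 1. Quantile normalization moved the share of higher calls by under 10 points in each comparison. For the changed results below the cause was not tested, and dim genes near the filter are limited by signal over background. For the response of control lines (12 genes), the count was 5 with a filter at the 75th percentile, 7 with a log2 difference of at least 1, 718 on 3 line differences, 46 with the replicate number as a block and 306 with each pair as a block. It was 0 to 18 without 1 line, with 0 by limma without control 1 or control 3 (241 and 523 at unadjusted p under 0.05), and 14 to 140 without 1 replicate. For the clones (60) it was 23 and 155 with pseudocounts of 1 and 64, 30 with quantile normalization, 20 without a filter, 115 at the 75th percentile, 103 with the median of a gene's probe sets, 0 with an intensity trend by limma (1872 at unadjusted p under 0.05), 2 with a log2 difference of at least 1, 0 with arrays as replicates with or without the number as a block (717 at unadjusted p under 0.05 with and 317 without it) and 162 with each pair as a block. Without 1 clone it was 6 to 239, the highest without clone 24, and without 1 replicate 0 to 224. For the difference of responses (85) it was 11 with a pseudocount of 1, 26 without a filter, 43 with median probe sets, 34 with a trend, 8 at log2 of at least 1, and 0 by limma with the number as a block (310 at unadjusted p under 0.05) or with each pair (1415). Without 1 line it was 0 to 109, the lowest without control 1, and without 1 replicate 0 to 1. For the DMSO levels (14) it was 7 and 82 with pseudocounts of 1 and 64, 35 with quantile normalization, 81 at the 75th percentile, 158 with median probe sets, 75 with a trend, 1 at log2 of at least 1, 44 with arrays as replicates and 630 with the number as a block besides. Without 1 line it was 0 to 2126, the highest without clone 1, and without 1 replicate 725 to 1221. For the MDV3100 levels (1062) it was 64 at log2 of at least 1 and 1639 with the number as a block, 8 (without control 1) to 2201 (without clone 1) without 1 line, and 1068 to 2326 without 1 replicate. The androgen-induced DMSO level (0.00234) was -0.0144 with a pseudocount of 1, -0.00159 with median probe sets and -0.173 to 0.178 without 1 replicate. The 23 list shifts became 1 with an estimated correlation and 12 to 14 without 1 replicate. Directions with a call reversed without replicate 2 for CCDC141 (-0.0773, against 2.15 without replicate 1) and AFF3 (-0.0402, against 1.88) in the difference of responses, ZNF385A (0.00372, against -0.912) in DMSO, and HPGD (-0.0791, against 3.56) and SLC4A4 (0.259, against -3.89) in MDV3100. They reversed without replicate 1 for KLHL1 (0.351, against -3.7 without replicate 2), RIPOR2 (0.847, against -3.77) and KLK3 (1.09, against -1.39) in MDV3100, and with median probe sets for PIGL (-0.00192) in DMSO.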

Other observations

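The genes, the family and the relation described here were chosen after their values were seen.

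Cancer-testis antigens of the MAGEA family, normally expressed in the testis, had signals that differed between the replicate sets for some members, and no member was called in both sets in DMSO. Under MDV3100 MAGEA1 was called in both, in opposite directions, at -1.95 (adjusted p = 0.000809) and 2.83 (adjusted p = 0.0311) by limma. In replicate 1, MAGEA1 was lower in the clones in DMSO, at -2.09 (adjusted p = 0.000193) by limma, and it stood at 2.87 (adjusted p = 0.0543) in replicate 2. MAGEA4 and MAGEA10 had DMSO signals of 171 ± 92 and 119 ± 73.6 in control lines of replicate 1 (SD, n = 3), and means of 2.8 and 5.81 in clones, below the filter signal of 12.1, where the pseudocount limits the size of a log2 difference. In replicate 2 they had 48.3 ± 82.3 and 25.8 ± 42.9 in control lines, and 145 ± 130 and 18.3 ± 7.59 in clones (SD, n = 7). MAGEA1 had a DMSO signal of 154 ± 18.1 in control lines and 24.8 ± 9.3 in clones of replicate 1 (SD, n = 3 and 7), and 69.4 ± 70.7 and 641 ± 290 in replicate 2. MAGEA12 was higher in the clones of replicate 2 by 0.97 (adjusted p = 0.0114) and stood at -0.29 in replicate 1 (adjusted p = 0.169). MAGEA6 differed by 0.04 and -0.04 in the sets, with DMSO signals of 2100 ± 57.8 in control lines and 2160 ± 79.7 in clones of replicate 1.

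In DMSO, ETV1 was low or nearly off on 1 replicate array and high on the other for every label but control 1 and clone 19. Those had 1293.3 and 1367.1, and 871.2 and 1607.9. UGT2B17 was low on 1 array and high on the other for some labels, among them control 2 and clone 1. In DMSO, ETV1 had signals of 1162.7 and 0.3 on the replicate 1 and replicate 2 arrays labelled control 2, and 0.3 and 738.6 on those labelled clone 1. ETV1 had a DMSO signal of 1270 ± 93.7 in control lines and 144 ± 322 in clones of replicate 1 (SD, n = 3 and 7). In replicate 2 it had 458 ± 788 and 1390 ± 349. The mean of 144 comes mostly from clone 19 and that of 458 from control 1. In MDV3100 its signals were 1220 ± 87.3 and 140 ± 318 in replicate 1 and 378 ± 642 and 1150 ± 228 in replicate 2. UGT2B17 had DMSO signals of 1090 ± 314 and 541 ± 297 in replicate 1 and 411 ± 503 and 1100 ± 240 in replicate 2, a difference of 2.14 in replicate 2 (adjusted p = 0.0403) and -1.37 in replicate 1 (adjusted p = 0.305).

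A hypothesis was that clones whose androgen-induced genes fell more also lost more proliferation transcripts. Over the 7 clones, Pearson r between the 2 list responses was -0.197 (exact permutation p = 0.675, adjusted 0.784 over 3 relations) and Spearman's rho -0.321 (exact permutation p = 0.498). Without the 2 clones farthest from the median r was 0.607, with 0.565 in replicate 1 and -0.938 in replicate 2, so it depends on single clones and on the set. In the replicate sets r was 0.394 in replicate 1 (exact permutation p = 0.382) and 0.163 in replicate 2 (exact permutation p = 0.784). The data neither bear the relation out nor exclude it.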
